A study of Homo sapiens with 3 samples.

How the data were processed

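The deposited values are signal per promoter window for the PAF1 and PHF5A libraries, in 1 table whose normalization is not given in the sources used here. The shortened name of its sheet ends in Relative_E, so a relative scale is possible, and what 1 unit of signal stands for stays open. Per the labels' protocols, fixation used EGS (1.5 mM) together with formaldehyde (0.4%), and libraries were made with the NEBNext Ultra II DNA kit. The submitters' processing notes name Trim Galore, Bowtie2 2.2.3, Picard, deepTools, bedtools and the GRCh38 (hg38) build. The order and settings of these tools are not given in the sources used here. The labels' protocol names IgG as a control, while the third library is titled input, and that library was not analysed here.

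The table lists 60123 windows, of which 60119 span 2500 bp, under 60075 Ensembl identifiers and 57997 symbols. The PAF1 signal equals a mean of whole numbers over the 150 bp bins that a window touches, cut to 2 decimals, within a tolerance of 0.0051 for 100% of windows, and PHF5A values do so after division by 1.00608. There were 17 bins in 20129 windows and 18 in 39990, and the 4 windows shorter than 2500 bp had other numbers of bins. The deposited signal was therefore not divided by the input window by window. A fragment can be counted in several bins, so bin sums are not numbers of reads.

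Windows of the same symbol (498 symbols with several) were averaged. The log2 scale used log2(signal + 0.5), centred on the median promoter of each library. Symbols were split into protein-coding-style (19182) and remaining symbols by their names, and biotypes were taken by symbol from a RefSeq table, which held the symbol of 32972 windows (54.8%) and marked 8879 windows as pseudogenes. Before the data were examined, the thresholds of 2-fold and top 5%, the 14 named genes that follow from the study's question, the gene lists and the rules for the other named genes were fixed. These rules took the highest protein-coding-style promoters of each library, those with the highest lower rank of both, those with the largest differences, and the 2 highest and the lowest members of each discussed list by the mean of both libraries. Promoters of lowest mean signal (10% of them), chromosome Y genes and XIST were left out of the ranking rules. The 2-fold count was foreseen relative to input, with ranks alone where the signal allows no such ratio. As it allows none, the count was set relative to the library's median promoter, a reference foreseen only as an alternative. The regional level, the median of 50 windows on each side with none nearer than 10 kb, was chosen after values were seen, as were the analyses without chromosome 6, without chromosomes 2 and 17, and of histones without pseudogene-named symbols.

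Gene lists were summarized by the median log2 signal of their members minus the median of their symbol class and placed among 10000 random lists of the same size and class (seed 1). A list outside the central 95% of random lists was counted as outside the range. Shares carry 95% Wilson intervals, which treat symbols as independent draws. Neighbouring promoters share signal, so these intervals are too narrow, and they hold no spread between libraries. Correlations are Spearman's rho across symbols or bins, which are not independent replicates.

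Counting errors used a dispersion of 4.32, estimated from the split of signal between the libraries over 51308 non-overlapping windows. This dispersion holds any true difference between the antibodies and so gives an upper bound of the error. The standard error of a window was the square root of dispersion times bin sum, divided by the number of bins and, for PHF5A, multiplied by 1.00608. A listed 0 was read as a signal of up to 3 counts per window times the dispersion, and these errors and floors cover counting alone. Near 0 the standard error shrinks with the bin sum and is too small, so a value below this floor is no more exact than a listed 0. On simulated data for 51308 windows, windows without a difference passed 3 standard errors in 0.215% of cases, a true spread of 0.30 in log2 ratios was recovered as 0.316, and 75.5% of 200 simulated lists of 30 genes shifted by 0.50 (log2) were found, with 2.0% of unshifted lists outside the range.

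Promoter base composition and mappability were not analysed here, so values of windows in families of near-identical gene copies are uncertain. Peaks were not called, and no test between groups was made, as each antibody has 1 library. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.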

Results

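Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in SW1990 cells, an established human pancreatic ductal adenocarcinoma line, in a population labelled SP. The series holds 3 libraries. In 1 library chromatin was precipitated with an antibody against PAF1, the subunit that gives the PAF1 transcription elongation complex its name and that the sample title calls PD2. In another the antibody was directed against PHF5A, a small protein of the SF3b splicing complex, and the remaining library was input chromatin. By its title, the series concerns PAF1, PHF5A and the RNA helicase DDX3 in the stemness of pancreatic cancer. The values analysed were the mean signals of the PAF1 and PHF5A libraries over 60123 promoter windows of hg38, each from 2000 bp upstream to 500 bp downstream of a transcription start site. The input library was not analysed here.

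The PAF1 and PHF5A libraries were of nearly equal depth. Their signal summed over the bins of all windows was 4810548 for PAF1 and 4891421 for PHF5A, and the median window held a sum of 73 and 75. The median promoter signal was 4.11 in the PAF1 library and 4.30 in the PHF5A library, with 90% ranges of 0.44 to 9.76 and 0.50 to 9.72. A value of 0 was listed for 2040 windows with PAF1 and 2051 with PHF5A. There was 1 library per antibody, so no difference between the antibodies has a replicate check, and values after ± are counting standard errors of a single library.

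The first question was which promoters carried the highest PAF1 signal. RNF5, which encodes an endoplasmic reticulum ubiquitin ligase (ENSG00000204308, promoter window on chromosome 6, 32176354 to 32178854), had the highest protein-coding value at 31.2 ± 2.82, 6.87 times the median promoter. TNF, which encodes the inflammatory cytokine (ENSG00000232810, chromosome 6, 31573567 to 31576067), followed at 28.2 ± 2.60, and AGPAT1, an acyltransferase of phospholipid synthesis whose window overlaps that of RNF5, had 24.6 ± 2.5. The centriole gene C2CD3 (chromosome 11, 74170710 to 74173210) had 24.1 ± 2.41, the Golgi SNARE gene GOSR1 (chromosome 17, 30475362 to 30477862) 23.9 ± 2.47 and AIF1, a gene of macrophages (chromosome 6, 31613184 to 31615684), 23.7 ± 2.38. The melanocortin receptor gene MC3R (chromosome 20, 56246732 to 56249232) had 23.3 ± 2.43 and the sorting nexin gene SNX32 (chromosome 11, 65831641 to 65834141) 22.9 ± 2.35.

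Of 57997 symbols, 4703 reached 2 times the median promoter in the PAF1 library, 8.11% (95% Wilson interval 7.89% to 8.33%). That interval treats symbols as independent draws. Neighbouring promoters share signal, so it is too narrow, and it holds no spread between libraries. Protein-coding-style symbols had a lower median than the remaining symbols, 3.64 against 4.38, and windows of pseudogenes had a median of 4.70. With protein-coding-style symbols alone, set against their own lower median, 1679 reached 2 times that median. The threshold is relative to the library's own median promoter and not to the input, so the count describes a spread of signal and not a set of bound promoters.

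The same promoters were then ranked in the PHF5A library. RNF5 was again the highest protein-coding promoter, at 37.0 ± 3.08 or 7.81 times the median promoter. NFKBIL1, which encodes a protein related to the NF-kB inhibitors (ENSG00000204498, chromosome 6, 31544870 to 31547370), had 27.5 ± 2.65, the organic anion transporter gene SLC22A7 (ENSG00000137204, chromosome 6, 43293694 to 43296194) 25.8 ± 2.5 and HLA-DOB, a class II antigen presentation gene (chromosome 6, 32816548 to 32819048), 24.2 ± 2.42. MC3R had 24.0 ± 2.48, C2CD3 23.6 ± 2.39, TNF 23.6 ± 2.39 and SNX32 23.4 ± 2.38. In the PAF1 library NFKBIL1 stood at 22.2 ± 2.37, SLC22A7 at 18.1 ± 2.09 and HLA-DOB at 21.3 ± 2.26, while in the PHF5A library AGPAT1 stood at 22.9 ± 2.42 and GOSR1 at 20.1 ± 2.27.

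In the PHF5A library 3923 symbols reached 2 times the median promoter, 6.76% (95% Wilson interval 6.56% to 6.97%). Protein-coding-style symbols again had the lower median, 3.91 against 4.49, with 4.69 for windows of pseudogenes. With protein-coding-style symbols ranked against their own median, 1500 reached the threshold. No replicate or input value stands beside these counts, and the interval has the limits given for PAF1.

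**Figure D1:**
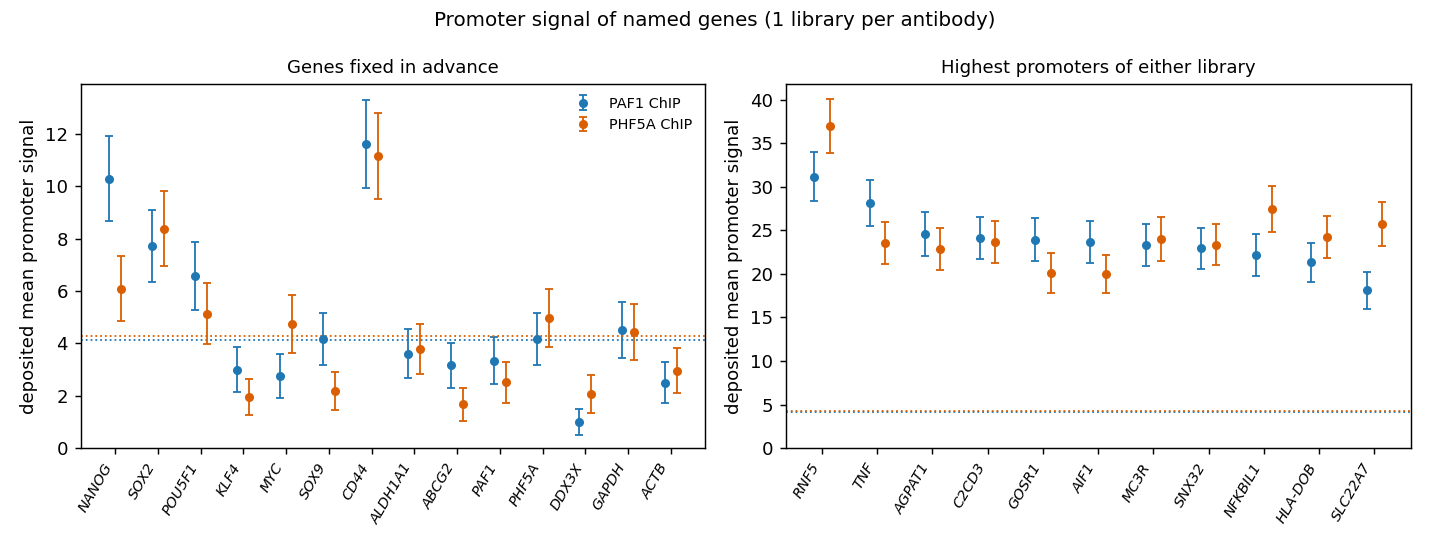
Deposited mean promoter signal (no unit, vertical axis) of the genes fixed in advance (left) and of the highest protein-coding promoters of either library (right), 1 point per library with its counting standard error, dotted lines marking the median promoters at 4.11 (PAF1) and 4.30 (PHF5A). CD44 and NANOG lay above the other genes fixed in advance in the PAF1 library, and RNF5 reached 31.2 with PAF1 and 37.0 with PHF5A.

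The series title points to stemness genes, so promoters of pluripotency factors and stem cell markers were read in both libraries. CD44, a surface glycoprotein used as a pancreatic cancer stem cell marker (ENSG00000026508, chromosome 11, 35136870 to 35139370), had the highest signal of the genes fixed in advance, 11.6 ± 1.67 with PAF1 and 11.2 ± 1.64 with PHF5A, or 2.63 and 2.43 times the median promoter. NANOG, a core pluripotency factor (ENSG00000111704, chromosome 12, 7785794 to 7788294), had 10.3 ± 1.62 with PAF1 (percentile 96.1) and 6.09 ± 1.25 with PHF5A (percentile 73.8). SOX2 (ENSG00000181449, chromosome 3, 181709924 to 181712424) had 7.72 ± 1.36 and 8.38 ± 1.42. POU5F1, which encodes OCT4 (chromosome 6, 31180231 to 31182731), had 6.58 ± 1.29 and 5.14 ± 1.15, above the median promoter but 0.596 and 0.474 times the level of its neighbourhood.

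Of the other stemness genes, KLF4 had 3.0 ± 0.849 with PAF1 and 1.95 ± 0.687 with PHF5A, MYC 2.76 ± 0.838 and 4.73 ± 1.10, and SOX9, a ductal progenitor factor, 4.16 ± 1.00 and 2.17 ± 0.726. The aldehyde dehydrogenase gene ALDH1A1 had 3.61 ± 0.931 and 3.8 ± 0.958, and the drug efflux pump gene ABCG2 3.16 ± 0.872 and 1.67 ± 0.636. Against their neighbourhoods ALDH1A1 had 1.41 and 1.46 times the regional level, while MYC had 0.467 and 0.704 times, SOX9 0.758 and 0.380 times, KLF4 0.745 and 0.502 times and ABCG2 0.814 and 0.459 times. Among promoters of the proteins under study, PAF1 had 3.33 ± 0.895 and 2.51 ± 0.780 and PHF5A 4.16 ± 1.00 and 4.97 ± 1.10. DDX3X had the lowest PAF1 signal of the genes fixed in advance, 1.00 ± 0.504 (percentile 8.39, 0.325 times the median promoter), and 2.07 ± 0.728 with PHF5A. Its neighbourhood on chromosome X was low as well, at 1.97 and 2.17, so DDX3X had 0.607 and 0.963 times the regional level. The housekeeping promoters GAPDH and ACTB had 4.52 ± 1.07 and 4.43 ± 1.07, and 2.5 ± 0.775 and 2.96 ± 0.846.

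As a group, the 27 pluripotency and stemness transcription factors had a median log2 signal of -0.10 against the median protein-coding-style symbol with PAF1 and 0.10 with PHF5A, percentiles 30.7 and 70.6 among 10000 random lists. In the PAF1 library 12 of the 27 lay above the class median, and in the PHF5A library 16. The orphan nuclear receptor gene ESRRB (10.8 ± 1.65 and 9.05 ± 1.52) and DPPA4, a chromatin factor of pluripotent cells (10.0 ± 1.55 and 7.04 ± 1.30), were highest, and TCF3 was listed at 0 with PAF1 and had 1.30 ± 0.577 with PHF5A. With fragments counted in several bins, a listed 0 allows a signal of up to 0.763 in a window of 17 bins and 0.720 in a window of 18 bins with PAF1, from counting alone. With PHF5A these floors are 0.767 and 0.725. Values below the floor, here and in what follows, are no more exact than a listed 0, whatever their standard error.

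The 23 pancreatic cancer stem cell markers had medians of -0.01 and -0.04 (percentiles 48.6 and 42.2), with 11 of the 23 above the class median in each library. Besides CD44, the tetraspanin gene CD9 was highest at 12.1 ± 1.76 and 8.99 ± 1.52, and CD24 was lowest at 2.38 ± 0.757 and 1.73 ± 0.647. By the mean in place of the median, the marker list lay 0.36 above its class with PAF1, percentile 97.7. The 8 measured genes of the PAF1 complex and DDX3 list had medians of -0.20 and -0.36 (percentiles 28.3 and 13.8), from CDC73 at 4.38 ± 1.03 and 5.86 ± 1.19 down to DDX3X. The 21 genes of the U2 snRNP, the splicing particle that holds PHF5A, had medians of -0.01 and 0.20 (percentiles 48.5 and 82.1). RBM17 (8.72 ± 1.45 and 8.49 ± 1.43) and SNRPB2 (6.83 ± 1.28 and 7.09 ± 1.31) were its highest members, while U2AF1, which has a near-identical copy in hg38, was listed at 0 in both libraries and is uncertain.

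The next comparison asked how far the PAF1 and PHF5A profiles coincided. By the lower of a promoter's percentile ranks in the libraries, RNF5, C2CD3, TNF and MC3R were the highest protein-coding promoters, followed by SNX32 and AGPAT1 at the same rank. Of the 2900 symbols in the top 5% of each library, 1778 were shared, 61.3% (95% Wilson interval 59.5% to 63.1%), where independent lists would share 145.0. Of the shared symbols, 219 lay on chromosome 6, 192 on chromosome 20, 178 on chromosome 11 and 176 on chromosome 14. Protein-coding-style symbols made up 441 of the 1778, or 24.8%, against 33.1% of all symbols. Spearman's rho between the libraries was 0.844 across the 57997 symbols, which are not independent replicates. For the same reason the Wilson interval of the shared part is too narrow.

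Part of this ranking followed the region. The highest median promoter signals of 5 Mb bins were found on chromosome 20 at 40 to 45 Mb, with 8.94 for PAF1 and 9.22 for PHF5A, and on chromosome 6 at 30 to 35 Mb, the major histocompatibility complex, with 8.83 and 9.72. RNF5, TNF, AGPAT1, AIF1, NFKBIL1 and HLA-DOB lie in the latter bin. By chromosome, medians were highest on chromosomes 20 (6.05 and 6.53) and 14 (5.94 and 6.15) and lowest on chromosomes 18 (2.38 and 2.51) and 21 (2.77 and 2.96). Across 5 Mb bins the medians of the libraries correlated with a rho of 0.959. A promoter's signal correlated with the median of its neighbours, 50 windows on each side and none nearer than 10 kb, with a rho of 0.517 in the PAF1 library and 0.547 in the PHF5A library.

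Set against that regional level, RNF5 had 3.08 times its neighbourhood with PAF1 and 3.42 times with PHF5A, TNF 2.63 and 2.09 times, and C2CD3 3.37 and 3.12 times. SNX32 stood furthest above its neighbourhood among the highest promoters, at 5.72 and 6.0 times, and SLC22A7 had 3.73 and 5.26 times. CD44 had 1.98 and 1.73 times its neighbourhood, NANOG 1.82 and 1.17 times and SOX2 1.27 and 1.42 times. After division by the regional level the libraries correlated with a rho of 0.768 and shared 58.7% of the top 5%. Without an input value for each window, these figures do not tell signal that an antibody enriched from signal that the chromatin gave in any library.

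**Figure D2:**
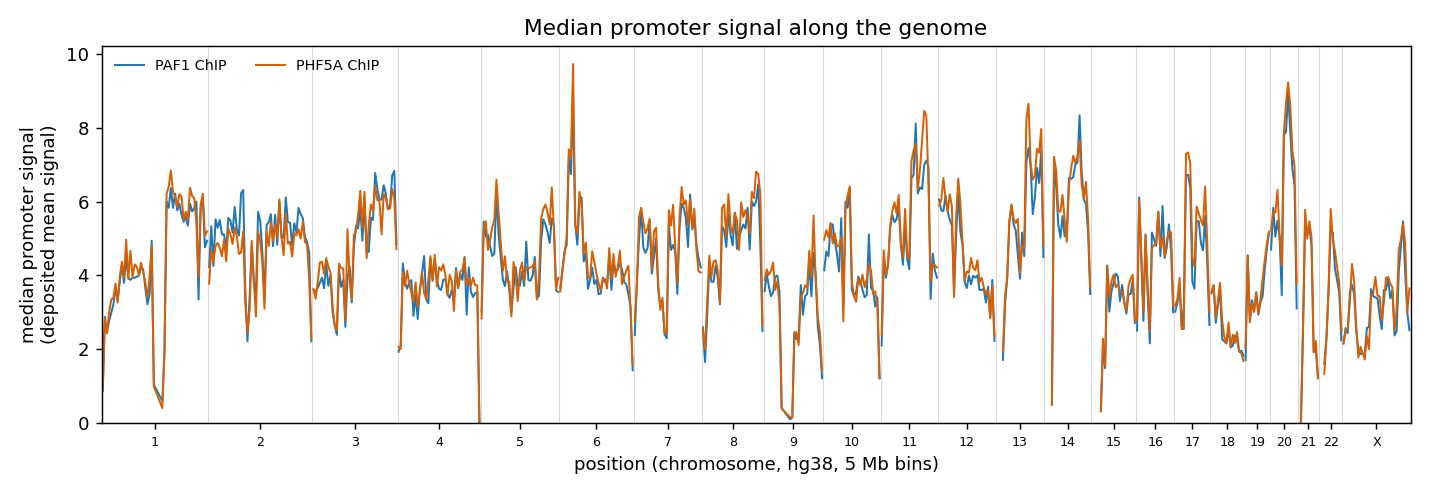
Median promoter signal of 5 Mb bins (vertical axis, deposited mean signal) along the chromosomes (horizontal axis, position in hg38) for the PAF1 and PHF5A libraries. Both lines are high on chromosome 6 at 30 to 35 Mb (8.83 and 9.72) and on chromosome 20 at 40 to 45 Mb (8.94 and 9.22) and are low along chromosome 18 (chromosome medians 2.38 and 2.51).

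Among the 38 gene lists, the highest promoter signals belonged to families of narrow tissue expression. The lists of taste and vomeronasal receptors, of keratin-associated and late cornified envelope genes, and of defensins and interferon alpha were set as silent controls. A list above its class is therefore not read here as a sign of binding. The 406 olfactory receptor genes had a median 0.57 (log2) above the median protein-coding-style symbol with PAF1 and 0.50 with PHF5A, above each of 10000 random lists, and 322 and 314 of them lay above the class median. OR6N1 had 17.6 ± 2.12 and 18.1 ± 2.15 and OR2AT4 14.8 ± 1.94 and 14.7 ± 1.94, while OR4F3, a member with near-identical copies, was listed at 0 in both libraries. The 31 taste and vomeronasal receptor genes lay 0.62 and 0.70 above their class, with TAS2R3 at 11.8 ± 1.68 and 11.2 ± 1.64, TAS2R42 at 11.9 ± 1.74 and 10.2 ± 1.61 and VN1R4 lowest at 4.38 ± 1.03 and 3.18 ± 0.877. The 111 keratin-associated and late cornified envelope genes, which act in hair and skin, lay 0.30 and 0.33 above it (percentiles 99.96 and 99.99), with LCE1B at 11 ± 1.63 and 10.2 ± 1.57, LCE1E at 11.1 ± 1.63 and 9.89 ± 1.55 and LCE1D lowest at 0.880 ± 0.462 and 0.550 ± 0.367.

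Divided by the regional level, olfactory receptors stayed 0.30 and 0.29 above their class, keratin-associated and late cornified envelope genes 0.18 and 0.20, and taste and vomeronasal receptors 0.27 (percentile 96.7) and 0.19 (percentile 91.8), which no longer left the central 95% of random lists. The 57 defensin and interferon alpha genes had unadjusted medians of 0.19 and -0.04 (percentiles 91.9 and 34.7) and regional ones of 0.59 and 0.31, and the PHF5A median turned to 0.36 without the promoters of lowest mean signal. Within this list DEFB121 (19.6 ± 2.17 and 17.9 ± 2.08) and DEFB116 (16.4 ± 1.98 and 16.04 ± 1.97) were highest, and DEFB105A, which lies in a duplicated cluster, was listed at 0 with PAF1 and had 0.160 ± 0.201 with PHF5A. The 478 C2H2 zinc finger genes had medians of 0.039 and 0.036, and regional ones of 0.12 and 0.11 (percentiles 99.7 and 99.8). Without matching, against the higher median of all symbols, they had -0.12 with PAF1. ZNF300 had 12.7 ± 1.74 and 16.8 ± 2.01 and ZNF572 11.2 ± 1.64 and 15.9 ± 1.962.

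The 88 symbols of the replication-dependent histone list, 14 of them named as pseudogenes, lay 0.23 above their class with PAF1 (percentile 98.7) and 0.19 with PHF5A (percentile 97.0, within the central 95%), but turned to -0.25 and -0.29 against their regional level and to -1.15 and -1.16 without chromosome 6. Without the pseudogene-named symbols, the other 74 had 0.17 and 0.12 (percentiles 93.8 and 85.1), within the range of random lists in both libraries. The highest members were the gene HIST1H2BN (8.27 ± 1.41 and 11.2 ± 1.64) and the pseudogene HIST1H2APS1 (8.55 ± 1.43 and 10.2 ± 1.57), both on chromosome 6, and HIST2H4A, a duplicated gene on chromosome 1, was listed at 0 in both libraries. Spliceosomal snRNA genes, 13 in number, had the lowest medians of all lists, -1.21 and -0.74 (percentiles 0.050 and 0.845). They ran from RNU6-8 (6.05 ± 1.24 and 4.02 ± 1.015) and RNU6-1 (3.83 ± 0.959 and 5.98 ± 1.20) to RNU1-4, listed at 0, and since snRNA genes have many near-identical copies their values are uncertain. The 1730 microRNA genes lay -0.082 and -0.089 against their class (percentiles 0.015 and 0), which was not outside the range of random lists without matching on class (percentiles 39.1 and 9.13). MIR570 (27.2 ± 2.56 and 24.3 ± 2.42) and MIR6833 (24.7 ± 2.43 and 21.7 ± 2.29), whose window overlaps that of AGPAT1, were the highest of them.

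Lists of broadly expressed genes lay on both sides of their class. Proteasome subunit genes (39) had medians of 0.22 and 0.20 and mitochondrial ribosomal protein genes (77) 0.14 and 0.11, between percentiles 84.0 and 91.7. The immunoproteasome genes PSMB9 (17.9 ± 2.08 and 20.3 ± 2.21) and PSMB8 (11.7 ± 1.68 and 14.7 ± 1.88) on chromosome 6 were the highest proteasome promoters. Cytosolic ribosomal protein genes, 84 in number, lay at -0.22 with PAF1 and -0.20 with PHF5A (percentiles 2.71 and 2.53), with RPS23 at 9.38 ± 1.50 and 10.7 ± 1.61, RPL23 at 7.35 ± 1.37 and 11.4 ± 1.70 and RPL10 listed at 0 in both libraries. The 31 housekeeping genes lay at -0.15 and -0.33 (percentiles 22.5 and 3.34), from RAB7A (10.2 ± 1.56 and 7.82 ± 1.37) and REEP5 (6.55 ± 1.25 and 7.04 ± 1.30) to ACTG1 (0.330 ± 0.283 and 0.780 ± 0.435), and like the ribosomal protein genes they stayed within the central 95% of random lists. Immediate early genes, whose transcription is controlled at the pause, lay at -0.15 with PAF1 (percentile 22.3) and -0.37 with PHF5A (percentile 1.98), with 9 of 30 members above the class median in the PHF5A library. BTG2 (7.05 ± 1.30 and 11.2 ± 1.65) and ATF3 (8.33 ± 1.41 and 8.43 ± 1.43) were their highest members and GADD45B (0.640 ± 0.406 and 0.880 ± 0.477) the lowest. The 32 transcription elongation and pause factor genes had -0.25 and -0.028 (percentiles 9.27 and 42.5), led by NELFE on chromosome 6 (15.7 ± 1.94 and 16.04 ± 1.97) and CDK12 (9.50 ± 1.51 and 10.0 ± 1.55), with NELFA lowest (0.550 ± 0.365 and 0.270 ± 0.260).

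Among signalling lists, the 19 Notch pathway genes had -0.52 with PHF5A (percentile 1.27) and -0.46 with PAF1 (percentile 3.41, within the central 95%), and the PHF5A median turned to 0.095 without the promoters of lowest mean signal. NUMB (5.76 ± 1.21 and 9.46 ± 1.56) and NOTCH4 (7.44 ± 1.34 and 9.94 ± 1.55) were highest. HES4 had 0.050 ± 0.116 and 0.160 ± 0.201, both below the floor of a listed 0. Wnt pathway genes (30) had -0.20 and -0.050, Hedgehog pathway genes (14) 0.11 and -0.064, NF-kB and cytokine genes (22) 0.053 and 0.28, MAPK feedback and ETS genes (23) 0.12 and 0.055, p53 targets (18) -0.038 and -0.082, and heat shock and unfolded protein response genes (24) -0.18 and -0.15, all between percentiles 15.01 and 92.5. Epithelial to mesenchymal transition genes (24) had 0.064 and 0.30 (percentiles 62.5 and 94.7), with the metalloprotease genes MMP14 (13.2 ± 1.78 and 12.0 ± 1.70) and MMP9 (10.6 ± 1.59 and 10.1 ± 1.56) highest and SMAD7 at 0 and 0.050 ± 0.116.

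Markers of the cell types of the pancreas did not separate by promoter signal. Ductal and epithelial genes, the lineage of the line (34 genes), had medians of -0.026 and 0.18 (percentiles 44.2 and 86.7), acinar genes (26) 0.045 and 0.053, endocrine genes (24) 0.078 and 0.12, and stromal and stellate genes (16) 0.14 and 0.21. Leukocyte genes (21) had 0.00 and -0.020, and neuronal genes (16) 0.14 and 0.018. The ductal genes HNF4A and CLDN1 had 8.58 ± 1.48 and 10.35 ± 1.63, and 9.58 ± 1.56 and 9.82 ± 1.59. The somatostatin gene SST of islet delta cells had 15.7 ± 1.94 and 10.34 ± 1.58, and the granulysin gene GNLY of killer lymphocytes 14.6 ± 1.93 and 12.1 ± 1.76.

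The remaining lists also stayed within the central 95% of random lists in both libraries. SR protein and hnRNP genes (31) had -0.24 and 0.036, glycolysis and hypoxia genes (28) -0.25 and -0.18, cell cycle and E2F targets (40) -0.13 and 0.036, and MYC targets of ribosome biogenesis (29) 0.00 and -0.13. HOX genes (39) had 0.028 and 0.070, and small nucleolar RNA genes (406) 0.037 and 0.0019. Of the 38 lists, 6 lay outside the central 95% of random lists with PAF1 and 7 with PHF5A, where lists of independent genes give 1.9. Random lists drew genes from the whole genome, while members of several families lie side by side and signal followed the region. For such families the random range is too narrow, and 1.9 is not the count expected by chance. Percentiles among random lists describe these 2 libraries and do not test a condition.

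**Figure D3:**
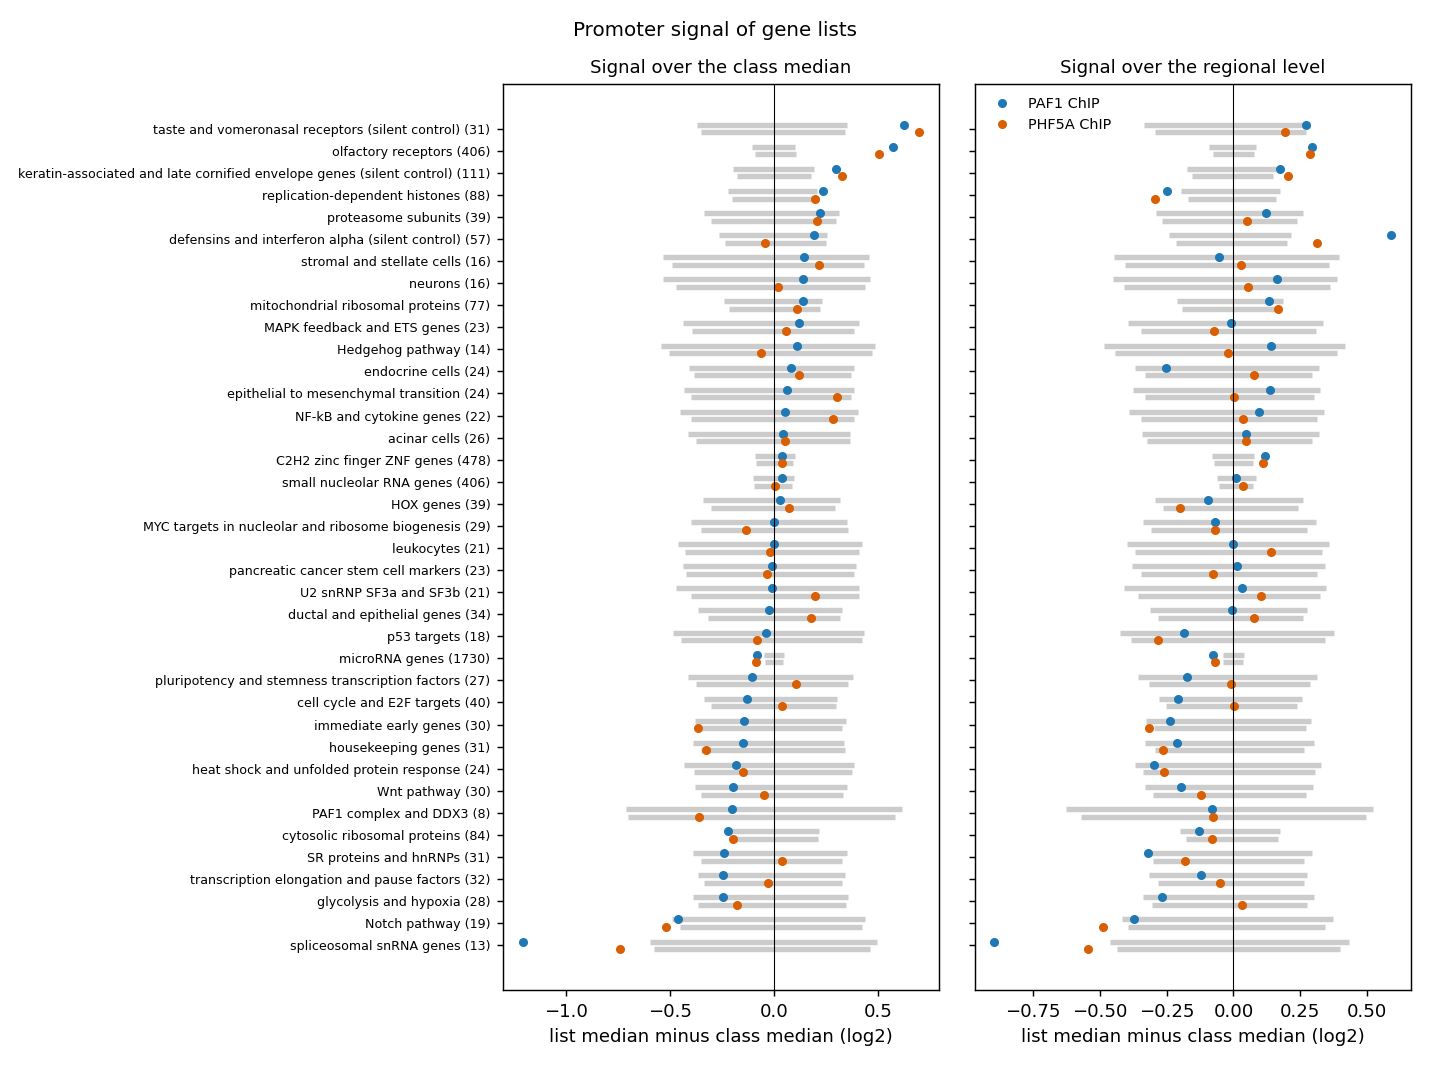
Median promoter signal of each of the 38 gene lists (number of genes in brackets) minus the median of its symbol class (log2, horizontal axes), before (left) and after (right) division by the regional level, for the PAF1 and PHF5A libraries, with grey bars for the central 95% of 10000 random lists. Olfactory receptors lay at 0.57 and 0.50 on the left and 0.30 and 0.29 on the right, and replication-dependent histones moved from 0.23 and 0.19 to -0.25 and -0.29.

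The last comparison set the PAF1 library against the PHF5A library. By the size of the difference, the promoters highest in PAF1 were those of the translation factor gene EIF4G3 (2.88 ± 0.833 with PAF1, 0.330 ± 0.285 with PHF5A), the transcription factor gene KLF9 (3.0 ± 0.849 and 0.390 ± 0.307), the RNA binding gene LSM4 (4.50 ± 1.04 and 0.830 ± 0.450) and the glutamate receptor gene GRIN3B (4.58 ± 1.08 and 0.940 ± 0.492). Those highest in PHF5A were the promoters of LMO4 (0.220 ± 0.231 with PAF1, 3.74 ± 0.951 with PHF5A), CEBPB (0.380 ± 0.306 and 4.02 ± 0.986), SREBF1 (0.290 ± 0.273 and 3.55 ± 0.953) and CHP1 (0.330 ± 0.283 and 3.68 ± 0.944), which encode a LIM-domain cofactor, a bZIP factor, a regulator of lipid synthesis and a calcium-binding protein. These 8 were picked as the largest differences, from 1 library per antibody, so their values describe the extremes and do not show a difference at any of them. Apart from LSM4 and GRIN3B, the lower value of each lay below the floor of a listed 0. Of the genes fixed in advance, NANOG had the clearest difference, 0.77 ± 0.37 (log2, 95% interval 0.040 to 1.50), and SOX9 had 0.86 ± 0.59 (-0.30 to 2.02). NANOG was picked as the clearest of these genes, and its interval covers counting error alone, without correction for that choice. With 1 library per antibody, the interval does not show a difference at NANOG.

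Across 17387 protein-coding-style symbols, 12 had more PAF1 signal and 37 more PHF5A signal by over 3 standard errors, where a normal distribution gives 23.5 in each direction, so the PAF1 side held fewer and the PHF5A side more than that. LMO4, CEBPB, SREBF1 and CHP1 are among the 37 by this measure, the error of the split between the libraries, although the 95% interval of the log2 ratio, which is wide at low signal, includes 0 for each of them. On the PAF1 side LSM4 (interval 0.32 to 3.62) and GRIN3B (0.26 to 3.49) are among the 12. EIF4G3 and KLF9 are not, and their intervals, built in the same way, include 0. As all were picked as extremes, these intervals do not show a difference. DAPL1 lay furthest on the PAF1 side at 3.71 standard errors and QARS furthest on the PHF5A side at -3.71. The counting error was set from the spread between these libraries, so it contains any true difference that most promoters share, and the total of such symbols is bound to lie near its expectation. By class, protein-coding windows outside chromosomes 2 and 17 lay at -0.063 ± 0.0041 (log2 of PAF1 over PHF5A) and pseudogene windows at 0.034 ± 0.0053. The differences above were measured from the split over all windows, so the class shift alone moves the counts of 12 and 37 towards PHF5A. In simulated data of this depth, 40.0% of windows with a 2-fold difference and all windows with a 4-fold difference passed 3 standard errors, so a difference of 2-fold at a single promoter was often not detectable.

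By list, defensin and interferon alpha genes stood 0.21 (log2) further towards PAF1 than their class (percentile 99.9) and microRNA genes 0.036 further towards PHF5A (median difference -0.036, percentile 0.190), while 36 lists stayed within the central 95% of random lists. Lists of independent genes give 1.9 of the 38. With differences of percentile ranks the defensin and interferon alpha list (percentile 94.9) and the microRNA list (percentile 13.3) were both inside that range, while a different list left it.

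Whole chromosomes differed by more than counting error. Promoter signal summed over chromosome 2 was 0.15 ± 0.0076 (log2) higher in the PAF1 library than in the PHF5A library, or 11.2%, and each of its 13 bins of 20 Mb lay on that side (0.11 to 0.19). On chromosome 17 the sum was -0.083 ± 0.0092, or -5.62%, with 0.051 ± 0.022 at 0 to 20 Mb and -0.075 to -0.16 in the other 4 bins. On chromosome 3 the bins at 160 to 180 Mb and 180 to 200 Mb had 0.13 ± 0.027 and 0.14 ± 0.021, while the chromosome had 0.035 ± 0.0085. The remaining chromosomes lay between -0.044 (chromosome 13) and 0.026 (chromosome 16). The promoter differences of genes on chromosomes 2 and 17 hold these shifts, and without both chromosomes 3 lists in place of 2 left the range of random lists.

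**Figure D4:**
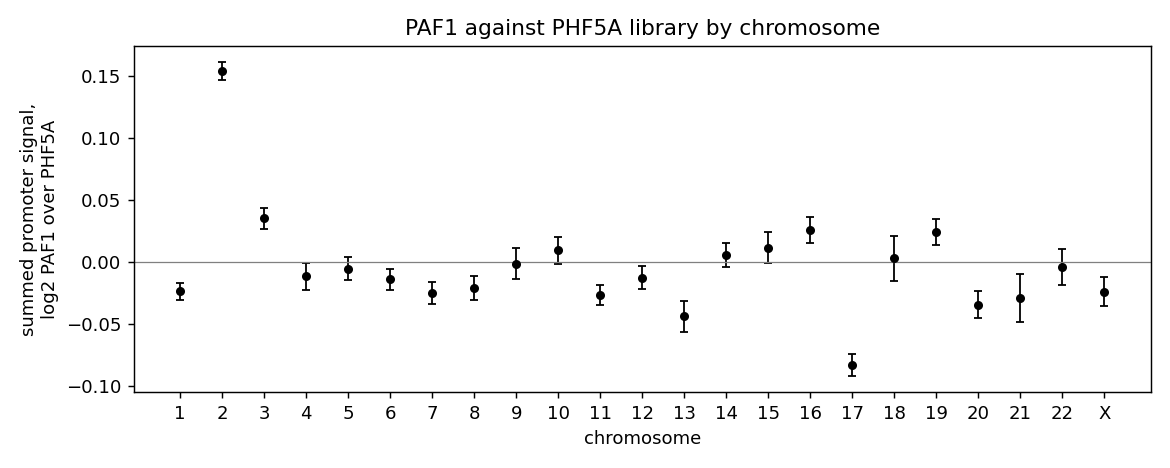
Signal summed over non-overlapping promoter windows of each chromosome (horizontal axis) as log2 of PAF1 over PHF5A after scaling to the same total (vertical axis), with counting standard errors. Chromosome 2 lies at 0.15 and chromosome 17 at -0.083, outside the range of the other chromosomes, from -0.044 to 0.035.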

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

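The regional level and the analyses without chromosome 6 or without chromosomes 2 and 17, and of histones without pseudogene-named symbols, were chosen only after the results were seen. No paired analysis was possible because each antibody has 1 library, and for the same reason no library could be left out. Matching on promoter base composition was not run, and neither was division by input, as all values used here are without it. Depth limits single promoters: a 2-fold rise in 1 library passed 3 standard errors in 40.0% of simulated windows, none of them of low signal.

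Counts of promoters at 2 times the median were 4703 (PAF1) and 3923 (PHF5A). They were 12645 and 11792 at 1.5-fold, 636 and 407 at 3-fold, 1679 and 1500 with protein-coding-style symbols only, and 47555 and 48604 for a deposited value of at least 2. The other settings gave 3353 to 5629 and 2695 to 4670. The shared part of the top 5% (61.3%) was 58.3% for the top 1%, 64.6% for the top 10% and 58.7% against the regional level. The Spearman correlation between the libraries (0.844) was 0.789 without the promoters of lowest mean signal and 0.768 against the regional level. The PAF1 minus PHF5A lists outside the range (2) were 1 with percentile ranks and 1 against the regional level. Of the list values of single libraries, 4 fell back inside the range by the mean, 4 without matching and 1 without the promoters of lowest mean signal. In the same settings 5, 7 and 2 others left the range without a change of direction.

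Some directions turned, and apart from the change of reference for zinc finger genes the cause was not tested. Stem cell markers with PAF1 had 0.36 by the mean. Replication-dependent histones had -0.25 (PAF1) and -0.29 (PHF5A) against the regional level, and -1.15 and -1.16 without chromosome 6. C2H2 zinc finger genes with PAF1 had -0.12 without matching, where the reference is the median of all symbols (4.11) and not the lower protein-coding-style median (3.64). With PHF5A, Notch genes had 0.095 without the promoters of lowest mean signal, and defensin and interferon alpha genes had 0.36 there and 0.31 against the regional level. Leaving out promoters of lowest mean signal selects on the measured signal itself. POU5F1 with PAF1 had -0.75 against the regional level. Of 66 values of named genes, 12 had the other sign there, among them POU5F1 with PHF5A (0.23 to -1.08), MYC with PHF5A (0.12 to -0.51), ALDH1A1 (-0.17 to 0.49 with PAF1, -0.16 to 0.54 with PHF5A) and GAPDH (0.12 to -0.38, 0.039 to -0.50). Before, these values of POU5F1 with PHF5A, MYC, ALDH1A1 and GAPDH were within 1 standard error of the median promoter. Of the 66, 33 kept their size against the regional level and 65 with a pseudocount of 0.1.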

Other observations

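Of the tests weighed here, those on copy number, on promoters of transcribed genes and on pseudogenes of chromosome 2 were set before their results were seen, and the others were chosen only after, as was the comparison of chromosome 2 windows with the same class elsewhere. The windows of this paragraph were also chosen after values were seen. The promoters furthest above their neighbourhood in both libraries included MGC50722 on chromosome 9 (15.4 ± 1.92 with PAF1 and 21.5 ± 2.28 with PHF5A, 8.65 and 11.3 times the regional level), CALY (13.6 and 13.6, 8.44 and 8.31 times), NUDT17 (11.8 and 13.4, 7.09 and 7.51 times) and ITGA10 (15.2 and 12.3, 7.37 and 5.89 times). BAGE5 had 9.84 and 7.45 times its regional level of 0.64 and 0.82. The other regional levels were also low, 1.335 and 1.45 for MGC50722, 1.165 and 1.2 for CALY, 1.23 and 1.345 for NUDT17, and 1.635 and 1.675 for ITGA10. The median promoters stood at 4.11 and 4.30, so these folds rest partly on low neighbourhoods. At the other end, 66 runs of at least 5 adjoining windows had values of at most 1.2 in both libraries beside a regional level of at least 2.0. Many of them lie in families of near-identical copies, such as RNA5S, USP17L, CT47A and REXO1L, where reads shared between copies make the values uncertain. This holds too for 2 further runs, which contain copied genes such as RIMBP3 and CXorf49. On chromosome 22, 27 windows from 18205415 had bin sums of 89 and 102 where the regional level gives 1595.0 and 1597.4, and on chromosome X 9 windows from 71689932 had 0 and 0 where it gives 543.2 and 536.0. In another run, 8 windows on chromosome 9 from 21890188 to 22012655, over the cell cycle inhibitor genes CDKN2A and CDKN2B, had bin sums of 28 with PAF1 and 25 with PHF5A, where the regional level gives 531.6 and 578.5. Their largest values were 1.11 and 0.710, and the windows flanking them had 4.38 and 4.47 with PAF1, and the cause was not tested.

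Signal levels along the genome were shared by both libraries. Median levels of pseudogene and coding windows in the same 5 Mb bins correlated with a rho of at least 0.697, as background reads that follow DNA copy number would give. Any other influence that acts on whole regions would give it too, so the correlation cannot tell copy number from these. The share of windows at 2 times their regional level in both libraries was 2.05% for coding and 4.32% for pseudogene windows, a ratio of 0.475. The prediction set for binding at promoters of transcribed genes was a higher share for coding windows, and it was not met. Coding windows were not sorted by expression, and base composition and mappability were not analysed. The ratio therefore cannot decide for or against such binding. The input library was not analysed here, and no biological explanation other than binding at transcribed promoters was tested.

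From promoter to promoter, the spread between the PAF1 and PHF5A libraries did not widen with depth as true differences of equal size at all depths would. The implied spread of true log2 ratios had an upper 95% bound of 0.0645, under the 0.20 that was set for antibody-specific binding at most promoters and within what counting error with fragments counted in several bins gives. This bound rests on the slope alone and takes the counting dispersion as equal at all depths. Dispersion was 3.84 at summed signals of 10 to 30, 4.41 at 60 to 100 and 4.18 at 200 to 300. Differences confined to windows of low signal would not raise the slope. Neither they nor single promoters that differ are ruled out by this bound.

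Chromosome 2 was higher and chromosome 17 lower in the PAF1 library. The chromosome 2 shift was 20.3 standard errors from 0, beyond counting error, and pseudogene windows on it were shifted by 0.150 (log2) against pseudogene windows elsewhere, about as coding windows were against coding windows elsewhere (0.162), and without that reference the shifts were 0.18 and 0.099, which does not point to binding at transcribed promoters. The gene-dense chromosomes 16, 19 and 22 had a mean shift of 0.0151, while a base composition bias was predicted to shift them like chromosome 17. Averages of whole chromosomes cannot exclude such a bias at single windows, as base composition was not analysed. Outside chromosomes 2 and 17, coding windows lay at -0.063 and pseudogene windows at 0.034, so the libraries also differed by window class. All 13 of 13 bins of 20 Mb on chromosome 2 were shifted up, but on chromosome 17 the bin at 0 to 20 Mb lay on the other side (0.051 ± 0.022), and as these bins hold the shift that prompted the question, a different chromosome content of the cells behind the libraries stays open. No biological explanation beyond these was tested.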
